A study of Homo sapiens with 4 samples.

How the data were processed

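RNA from parental and vemurafenib-resistant A375 melanoma cells was sequenced as polyA-selected, strand-specific, paired-end libraries, per the labels' protocols, with 2 libraries per group. The deposited values are raw counts per gene, 1 file per library. The sample numbers in the names of the 2 resistant files (5 and 6) differ from those in the labels (3 and 4), so each file was taken as the library of the record it was deposited under. Per the file headers, counts came from featureCounts 2.0.0 run with an annotation and an output file as its sole options, on duplicate-marked alignments, against GENCODE release 42. By that program's defaults, reads were counted without regard to strand, both mates of a pair were counted singly, reads that mapped to several places or to several genes were left out, and marked duplicates were kept. Reads of a gene and of its antisense partner can therefore not be told apart, and reads in the shared stretch of 2 overlapping genes were dropped. Exons overlapping another gene on the opposite strand made up 28.6% of the exonic bases of DUSP6, 27.2% of NGFR, 26.1% of UCA1, 24.6% of VIM, 21.1% of PAPPA, 11.8% of FUT8, 11.4% of VIPR1, 10.4% of CCND1 and 6.0% of BRAF. Alignment with STAR, counting with featureCounts, DESeq2 and the GRCh38 build are named in the submitters' processing notes. The submitters' treatment of libraries with sorafenib and pioglitazone, and the glycan measurements, were not analysed here.

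A further table gives a gene symbol and a log fold change with no header. Its values are log2 by comparison with the counts, but the authors' deposited table names no comparison, so it entered no test and named no gene. It is described once among the other observations.

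Each count of control replicate 1 was even (0 odd values), whereas 62.1%, 64.5% and 63.3% of counts from 1 to 10 were even in the other libraries, and 63.9% in control replicate 1 after halving. The counts were tested as deposited, and an alternative with that library halved was added after seeing the data. Mates were counted singly, so even counts are common in each library and the number of independent fragments is about the total divided by 2, or by 4 in control replicate 1 if its alignments were counted 2 times. A count of 3 corresponds to 0.0415 and 0.0344 CPM in control replicates 1 and 2 and to 0.0441 and 0.0352 CPM in resistant replicates 1 and 2. Such floors cover counting error only. Counts differed between replicates far beyond sampling noise (chi-square per degree of freedom 121 in the controls, 64.2 in the resistant libraries), so no library was taken as deposited 2 times.

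Of 62649 gene identifiers, 62625 matched a symbol, and 58225 had a gene type in GENCODE release 29, the annotation at hand. Coordinates are 1-based on GRCh38. Genes were filtered with edgeR's filterByExpr at its defaults (24961 kept), scaled with TMM factors and tested with edgeR's quasi-likelihood F test with group as the sole term (R 4.3.3, edgeR 4.0.16, limma 3.58.1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.065, a biological coefficient of variation of 25.5%, with 2 residual and 5.69 prior degrees of freedom. CPM are TMM-normalised, and log2 fold changes are fitted values, resistant over control. SE is the size of the fold change divided by the square root of F. In 8 changed genes both libraries of a group had 0 counts, and none of these is named.

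Fixed before the data were examined were 41 gene lists, tested with limma's camera on the edgeR fit with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. The text names the 12 genes with the highest and the 12 with the lowest fold change among changed genes with a symbol that is not a clone name, a mean of at least 10 CPM in the higher group and both resistant libraries on the same side of both controls. It also names, in each list past the test or with at least 5 changed members, up to 2 changed members per direction with at least 5 CPM, and 20 genes fixed whatever their values. One gene that the rule names is not reported here. Genes outside this rule are said to be named after their values were seen, or serve as examples of a list adjusted over the list alone.

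Positions were examined after the fold changes had been seen, in bins of 10 Mb with at least 10 protein-coding genes of at least 3 CPM in the higher group (11813 genes, 289 bins). Fisher's exact tests compared called genes inside and outside each segment. Tested genes with at least 1 CPM in the higher group that these bins left out (not protein coding, or under 3 CPM) served to check the segments.

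The edgeR and camera steps were tested on simulated counts for resistant against control (23866 genes tested). The edgeR test recovered 33 of 67 genes changed 2-fold (49.3%), 66 of 67 changed 4-fold and 66 of 66 changed 8-fold, and called 28 of 24761 unchanged genes, which made up 14.5% of its calls, above the nominal 5%. DESeq2 recovered 42 of 67 at 2-fold and called 52 unchanged genes (23.0% of its calls). Camera called a planted list of 24 genes lowered 2-fold (adjusted p = 1.33e-56) and 0 of 100 unchanged lists. These simulated genes varied independently, so that list check does not cover correlated lists.

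Alternatives were other scalings (RLE, library size alone, upper quartile), DESeq2 1.42.0, limma-voom, no filter or a stricter one (1 CPM in 2 libraries and a total of 100), protein-coding genes alone, each replicate left out, the replicate number as a block, thinned counts, glmTreat against a 2-fold change, and 4 added after seeing the data. With 1 library left in a group, it was assumed to vary like the other group. Bins and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.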

Results

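Gene counts from polyA RNA-seq were analysed for 4 libraries of A375, a human melanoma cell line that carries an activating BRAF mutation. Parental cells served as the control (2 libraries). The other 2 libraries came from cells made resistant to vemurafenib, an inhibitor of the mutant BRAF kinase, by raising its concentration weekly from 0.1 to 6.4 µM. The labels do not say whether vemurafenib was present at harvest. Counts assigned to genes totalled 72290468 in control replicate 1, 87178097 in control replicate 2, 68022689 in resistant replicate 1 and 85197524 in resistant replicate 2. Each count in control replicate 1 was an even number, as if its alignments had been counted 2 times, which would put its true total at 36145234.

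The comparison of resistant with parental cells asks which transcripts differ between cells that adapted to the drug and the line they came from. In resistant cells 144 of 24961 tested genes were higher and 128 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 266 of these 272 genes differed at least 2-fold. The prohormone convertase gene PCSK1 was 15.8-fold higher, and TMPRSS15, which encodes enteropeptidase, was 81.9-fold lower. The adhesion receptor gene ADGRF1 was 228-fold lower on 6 and 43 counts in the resistant libraries, with a log2 fold change between -9.70 without resistant replicate 2 and -6.91 without control replicate 1. BRAF itself was 2.36-fold higher, together with its neighbours on chromosome 7, and PPARG, a nuclear receptor gene, was 4.39-fold lower. The count of changed genes varied widely with 1 library left out, where the spread came from the other group alone. Such counts mix a change of effect with a change in that estimate, so they do not show which library the differences depend on. The series calls the libraries biological replicates without saying that they were separate cultures, so the p-values measure the spread between these libraries, which may be technical in part.

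Control replicate 2 lay closer to the resistant libraries than control replicate 1 did. Over 10089 genes with a mean of at least 10 CPM (counts scaled to the library total with TMM factors), Pearson's r of log2 CPM across genes was 0.962 between the controls and 0.978 between the resistant libraries. Control replicate 2 correlated with resistant replicate 2 at 0.966 and with resistant replicate 1 at 0.959, against 0.923 and 0.916 for control replicate 1. Genes are not independent replicates, so these values carry no p. The log2 difference between replicates had an SD across genes of 0.400 in the controls and 0.304 in the resistant cells. The groups did not overlap in 11132 genes (44.6%), where chance gives 33.3% for 2 against 2.

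Of the 12 genes named for the highest fold changes, PCSK1 (ENSG00000175426.11, chromosome 5) rose from 1.13 ± 0.295 to 18.0 ± 4.02 CPM (mean ± SD, n = 2 per group), a log2 fold change of 3.98 ± 0.31 (SE, edgeR adjusted p = 0.0118). PTPRN, which encodes a protein of dense-core secretory vesicles, had a log2 fold change of 3.23 ± 0.41 (edgeR adjusted p = 0.0229). ACAN, the gene of the cartilage proteoglycan aggrecan, went from 2.94 ± 2.10 to 30.5 ± 15.9 CPM (edgeR adjusted p = 0.0432). NFASC, which encodes the neuronal adhesion molecule neurofascin, rose 5.16-fold (log2 2.37 ± 0.22, edgeR adjusted p = 0.012). The netrin receptor gene UNC5B rose 4.72-fold, the growth factor gene BMP6 4.48-fold and PAPPA, which encodes a protease of insulin-like growth factor binding proteins, 4.41-fold. The others of the 12 were WSCD1 (14.5-fold), TP53I11 (12-fold), PDE4B, a cyclic AMP phosphodiesterase gene (6.90-fold), TSPAN11 (5.66-fold) and LRP3 (4.82-fold). Without resistant replicate 2, PCSK1 (adjusted p = 0.0325) and NFASC (0.0458) passed the edgeR threshold, and the adjusted p of the other 10 genes ranged from 0.0608 for TP53I11 and LRP3 to 0.189 for PAPPA. The fold changes, not on the log2 scale, of 6 genes moved by more than 1.5-fold from the fit of all libraries with 1 left out, each highest without control replicate 2. On the log2 scale WSCD1 ranged from 3.14 to 5.44, ACAN from 2.71 to 4.39, PTPRN from 2.73 to 4.04, UNC5B from 1.82 to 2.84, BMP6 from 1.74 to 2.77 and PAPPA from 1.69 to 2.83. The lowest value was that without control replicate 1, or for ACAN without resistant replicate 1.

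Of the 12 genes named for the lowest fold changes, ADGRF1 (ENSG00000153292.16, chromosome 6) fell from 71.6 ± 47.9 to 0.302 ± 0.308 CPM (n = 2 per group), a log2 fold change of -7.83 ± 0.78 (SE, edgeR adjusted p = 0.012). TMPRSS15 (ENSG00000154646.9, chromosome 21) had a log2 fold change of -6.36 ± 0.25 (edgeR adjusted p = 3.06e-04). KISS1, the gene of the peptide kisspeptin, fell 37.3-fold, from 34.3 ± 27.3 to 0.903 ± 0.879 CPM. VIPR1, a receptor gene for vasoactive intestinal peptide, fell 26.3-fold, the membrane glycoprotein gene CDCP1 26.1-fold and the tyrosine kinase gene BMX 20.3-fold. The abundant integrin gene ITGB4 fell from 1452 ± 42.9 to 185 ± 100 CPM (log2 -2.97 ± 0.36, edgeR adjusted p = 0.0206). SOX9, a transcription factor gene of the neural crest lineage, fell from 24.2 ± 5.91 to 3.42 ± 1.04 CPM (edgeR adjusted p = 0.014). UCA1, a long noncoding RNA, HOXC12, the metalloprotease gene ADAMTS6 and TM4SF18 fell between 7-fold and 11-fold. Without resistant replicate 2, ADGRF1 (adjusted p = 0.0439), TMPRSS15 (0.0159) and ITGB4 (0.0175) passed the edgeR threshold, and the other 9 ranged from 0.0571 for ADAMTS6 to 0.188 for TM4SF18. Fold changes, again not on the log2 scale, moved by more than 1.5-fold with 1 library left out for ADGRF1, as given above, and for 6 others. KISS1 had a log2 fold change of -6.92 and VIPR1 of -5.53 without resistant replicate 2, and -4.02 and -3.97 without control replicate 1. BMX and TM4SF18 had -4.97 and -3.37 without control replicate 2, and -3.22 and -1.87 without control replicate 1. CDCP1 had -5.33 without control replicate 1 and -3.57 without control replicate 2, and ITGB4 had -3.67 without resistant replicate 2 and -2.50 without resistant replicate 1.

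**Figure D1:**
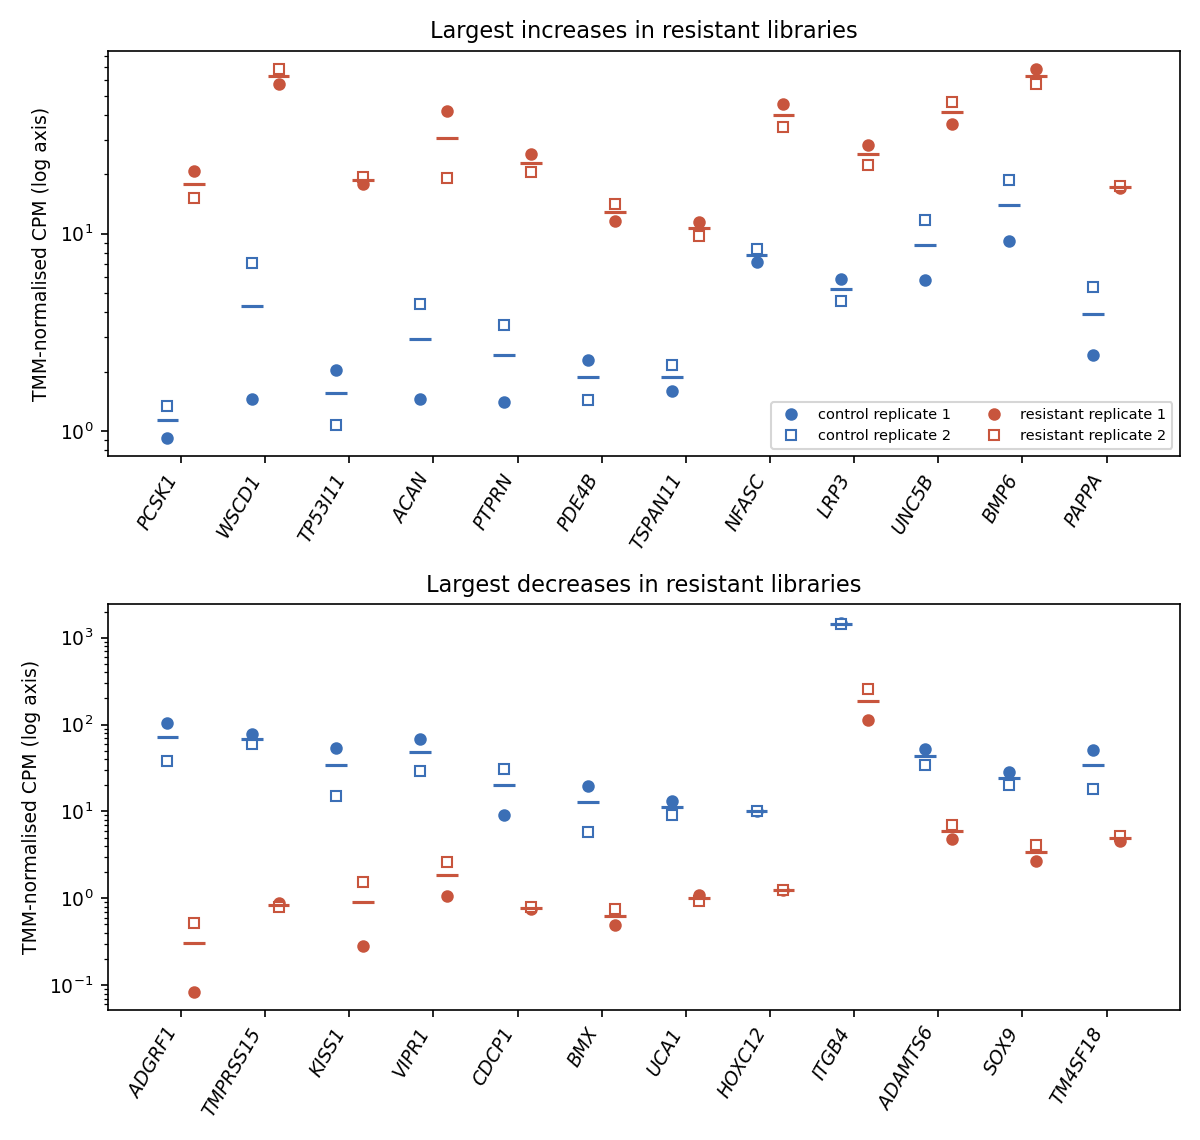
TMM-normalised CPM (log axis) of the 12 named genes with the highest and the 12 with the lowest fold change, with 1 point per library and group means as bars. PCSK1 had 0.922 and 1.34 CPM in the control libraries against 20.8 and 15.1 in the resistant ones, and TMPRSS15 77.9 and 59.0 against 0.872 and 0.798.

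Changed genes were more frequent in parts of 2 chromosomes than elsewhere, an arrangement looked for after the fold changes had been seen. On chromosome 7 (GRCh38) from 140 to 160 Mb, 69 of 73 expressed protein-coding genes had a positive fold change, with a median log2 fold change of 0.99 (interquartile range 0.74 to 1.22), or 1.98-fold. In this stretch 29 genes were called higher, against 77 of 11740 elsewhere (two-sided Fisher's exact test, p = 9.37e-42, odds ratio 99.8). BRAF (ENSG00000157764.14, chromosome 7, 140719327 to 140924929) lies in it and rose from 56.3 ± 9.59 to 133 ± 21.2 CPM (n = 2 per group, log2 1.24 ± 0.20, edgeR adjusted p = 0.0415). Without resistant replicate 2, BRAF had a log2 fold change of 1.06 and an edgeR adjusted p of 0.199. On chromosome 3 from 0 to 100 Mb, 324 of 341 genes had a negative fold change, with a median of -0.62 (interquartile range -0.80 to -0.44). There 13 genes were called lower, against 60 of 11472 elsewhere (two-sided Fisher's exact test, p = 1.39e-07, odds ratio 7.54). The segments were chosen from the fold changes of these same genes, and neighbouring genes are not independent. Both p-values therefore describe the arrangement only. Each library agreed in sign with its group: the segment median relative to the gene means was -0.44 and -0.49 in the controls and 0.46 and 0.46 in the resistant libraries on chromosome 7, and 0.33, 0.29, -0.34 and -0.28 on chromosome 3. Elsewhere, 278 bins of 10 Mb had medians from -0.408 to 0.591, and 1 of them, on chromosome X with 11 genes, reached 0.5 in size. Smaller runs of adjacent bins were not tested. Medians were -0.341, -0.21, -0.408 and -0.204 on chromosome 12 from 70 to 110 Mb, and -0.328 and -0.265 on chromosome 18 from 0 to 20 Mb. They were positive, from 0.077 to 0.449, on chromosome 2 from 200 to 250 Mb. PPARG, VIPR1, CDCP1, WNT5A and MITF lie in the chromosome 3 segment.

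**Figure D2:**
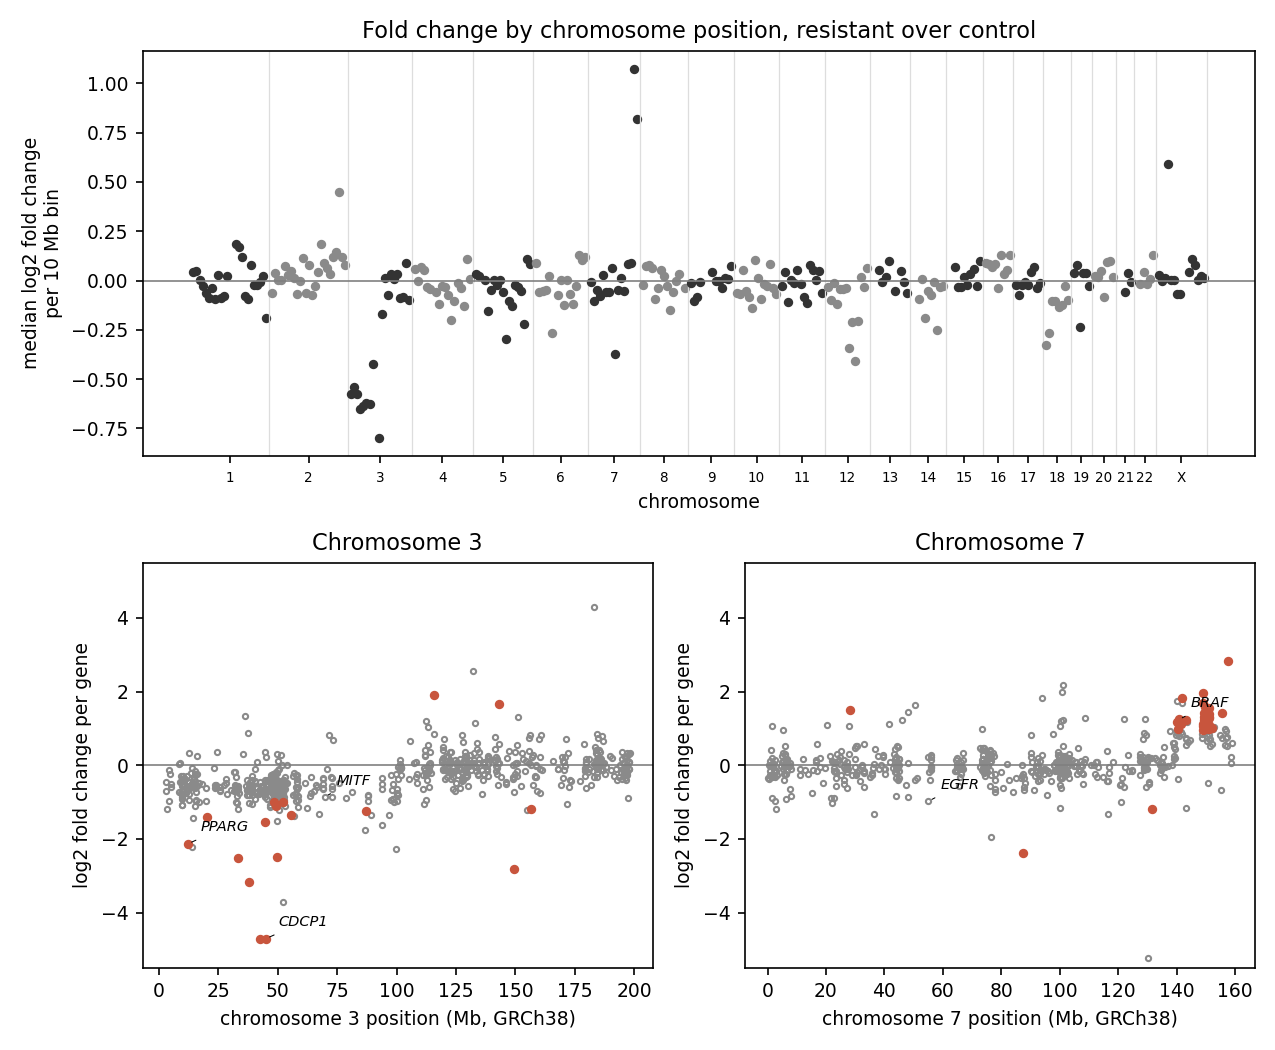
Median log2 fold change of resistant over control in bins of 10 Mb along the genome, each holding at least 10 protein-coding genes with a mean of at least 3 CPM in the higher group. The bins of chromosome 7 from 140 to 160 Mb lie above the rest of that chromosome, with a segment median of 0.99, and those of chromosome 3 up to 100 Mb lie below 0, with a segment median of -0.62.

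Melanoma cells under BRAF inhibition can shift between a pigment-cell state and a dedifferentiated state, and markers of both were fixed before the data were examined. Of 24 dedifferentiation genes, 2 fell and none of the 24 rose over all genes tested with edgeR, while adjusted over the list alone 6 fell and 4 rose. The 2 were SOX9 and the ligand gene WNT5A, which fell from 57.6 ± 6.66 to 22.6 ± 5.57 CPM (edgeR adjusted p = 0.0415; 0.196 without resistant replicate 2). The list median was -0.43 and the list fell in limma's camera test (adjusted p = 0.0236), with an adjusted p = 0.704 under an estimated correlation. That list missed the camera threshold without control replicate 2 (adjusted p = 0.196) and without resistant replicate 1 (0.429), and its median ranged from -0.86 to -0.17 with 1 library left out, at its extremes without resistant replicate 2 and without control replicate 1. The receptor genes AXL (log2 -0.47, edgeR adjusted p = 0.619), NGFR (-0.51, 0.692), PDGFRB (-0.65, 0.347) and EGFR (-0.98, 0.0982) did not pass. AXL had a log2 fold change of -0.03 without resistant replicate 1 and -1.09 without resistant replicate 2, and NGFR one of 0.02 and -1.35. With 1 library left out, the log2 fold change ranged from -1.20 to -0.71 for EGFR and from -0.95 to -0.27 for PDGFRB. None of 22 melanocytic genes passed edgeR, over all genes or adjusted over the list alone, or DESeq2, and 2 had an unadjusted edgeR p under 0.05 (list median 0.14, camera adjusted p = 0.362). Several were barely expressed, among them TYR (0.188 CPM in controls and 0.140 in resistant cells), DCT (0.249 and 0.136) and IRF4 (0.255 and 0.135). PMEL (1.67 and 1.30) and MLANA (1.30 and 1.73) were low too, while ERBB3 had 368 and 396 CPM. These genes were named after their values were seen, and for the low ones a missing call says little. MITF, the master transcription factor of pigment cells, had a log2 fold change of -0.86 ± 0.37 (edgeR adjusted p = 0.371; log2 -1.40 to -0.35 with 1 library left out), and SOX10 one of -0.015 ± 0.248.

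Transcripts controlled by the MAPK pathway, which vemurafenib blocks, did not pass as a group. Of 22 such genes none passed over all genes tested with edgeR, 3 had an unadjusted p under 0.05, and 2 rose adjusted over the list alone and with DESeq2 (list median 0.06, camera adjusted p = 0.309). DUSP6, a feedback phosphatase gene, had 216 ± 71.6 CPM in controls and 202 ± 30.7 in resistant cells (log2 -0.10, edgeR adjusted p = 0.926). SPRY4 had a log2 fold change of 0.36 (edgeR adjusted p = 0.762; log2 -0.15 to 1.16 with 1 library left out) and the cyclin gene CCND1 one of -0.23 (0.79). For 32 receptor tyrosine kinases and ligands the list median was -0.08 (camera adjusted p = 0.973), with 0 calls over all genes in edgeR, 13 at an unadjusted p under 0.05, 4 higher and 3 lower adjusted over the list alone, and 4 higher and 2 lower with DESeq2.

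Sorafenib and pioglitazone, drugs that the series pairs with resistance, act on kinases and on PPARG. Among 14 genes of sorafenib's kinase targets, BRAF alone passed over all genes in edgeR, while 7 had an unadjusted p under 0.05. Adjusted over the list alone 3 rose and 2 fell, and DESeq2 called 3 higher and 1 lower (camera adjusted p = 0.915). PPARG (ENSG00000132170.24, chromosome 3, 12287368 to 12434356) fell from 69.5 ± 4.64 to 15.8 ± 7.14 CPM (n = 2 per group, log2 -2.13 ± 0.30, edgeR adjusted p = 0.0312). Of 20 genes of the PPARG list, PPARG and the lipid droplet gene PLIN4 fell over all genes (PLIN4 log2 -2.58, edgeR adjusted p = 0.0212, and 0.133 without resistant replicate 2; named after its values were seen), and the list missed the camera threshold (adjusted p = 0.0521, list median -0.22). Adjusted over the list alone, 3 of its genes fell and 2 rose, and DESeq2 called 3 lower and 2 higher.

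**Figure D3:**
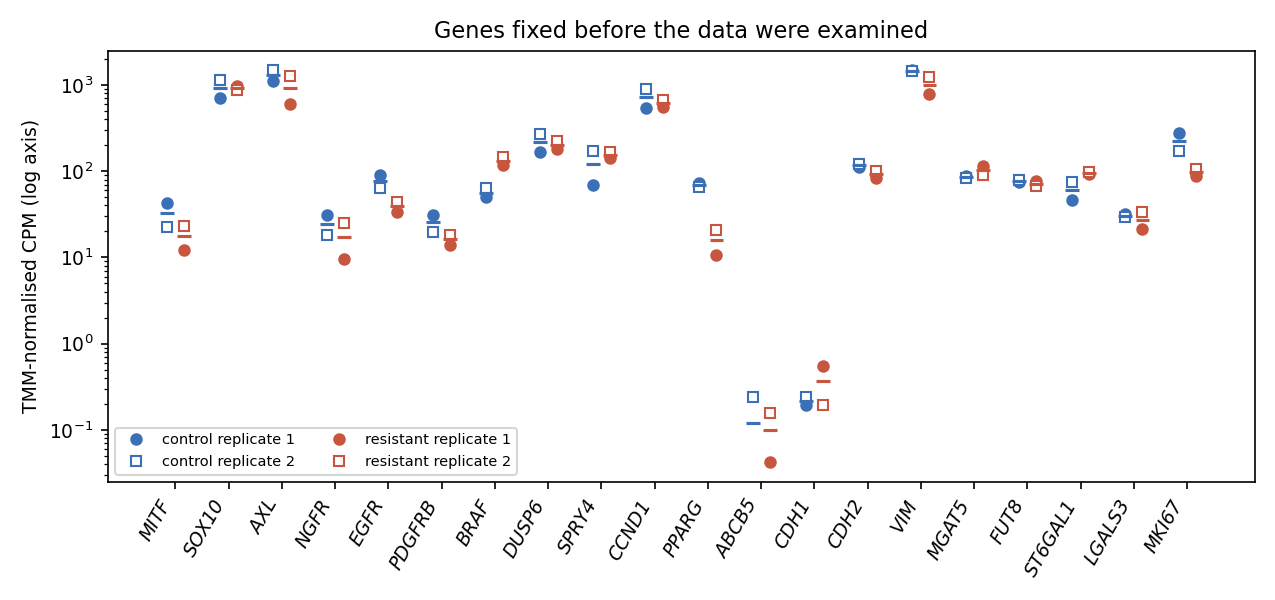
TMM-normalised CPM (log axis) of the 20 genes fixed before the data were examined, with 1 point per library and group means as bars. BRAF was higher and PPARG lower in both resistant libraries, and the 0 CPM of ABCB5 in control replicate 1 lies off the axis.

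Genes of the G2 and M phases of the cell cycle were lower in resistant cells as a group. All 24 had a negative fold change, with a median of -1.17 (limma camera adjusted p = 2.2e-19). With an estimated correlation, which was 0.956 for this list, the camera adjusted p = 0.704. None of them passed over all genes in edgeR, while 23 had an unadjusted p under 0.05, 23 fell adjusted over the list alone and 13 fell with DESeq2. MKI67, a proliferation marker, had 224 ± 74.9 CPM in controls and 97.8 ± 13.4 in resistant cells (n = 2 per group, log2 -1.20 ± 0.25, edgeR adjusted p = 0.0772). Its log2 fold change ranged from -1.50 without control replicate 2 to -0.81 without control replicate 1 over the fits with 1 library left out. Without control replicate 1 the list median was -0.69 (camera adjusted p = 3.14e-14). Of 24 S phase genes 21 had a negative sign (median -0.35, camera adjusted p = 0.00468; with an estimated correlation adjusted p = 0.817). The S phase list missed the camera threshold without control replicate 1 (median -0.03, adjusted p = 0.645) and without resistant replicate 2 (-0.11, 0.48), and its median was -0.69 without resistant replicate 1 and -0.60 without control replicate 2. None of its genes passed in edgeR over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05 and 1 fell with DESeq2.

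Cholesterol and lipid synthesis genes fell as a group: 26 of 29 had a negative sign, with a median of -0.55 (camera adjusted p = 7.38e-06; with an estimated correlation adjusted p = 0.704). Adjusted over the list alone 4 fell in edgeR, and 4 fell with DESeq2. Without control replicate 1, the controls' more distant library, the list median was -0.15 (camera adjusted p = 0.103).

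Endoplasmic reticulum chaperone genes rose as a group, with a positive sign in 18 of 20 and a median of 0.69 (camera adjusted p = 6.08e-07; with an estimated correlation adjusted p = 0.704). PDIA4, which encodes a disulfide isomerase, was the 1 member past edgeR's threshold over all genes (164 ± 9.82 to 645 ± 347 CPM, log2 1.97 ± 0.35, edgeR adjusted p = 0.05 after rounding up), and it lies in the chromosome 7 segment. DESeq2 called 5 members of the list higher. Without resistant replicate 1 the list median was 0.37 (camera adjusted p = 0.0021) and PDIA4 had a log2 fold change of 1.29. Adjusted over the list alone 6 rose, among them HSPA5, the main chaperone of the compartment, with 639 CPM in controls and 1641 in resistant cells (edgeR adjusted p over all genes 0.132). With 1 library left out, the log2 fold change of HSPA5 ranged from 0.84 without resistant replicate 1 to 1.81 without control replicate 2. The amino acid stress list had a positive sign in 25 of 27 genes and a median of 0.38 (camera adjusted p = 6.3e-04; with an estimated correlation adjusted p = 0.717), and none of its genes passed in edgeR over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 1 higher with DESeq2. Its median was 0.81 without control replicate 2, and its camera adjusted p was 0.425 without control replicate 1 (median 0.07) and 0.0642 without resistant replicate 2. The list of NF-kB and inflammatory cytokine genes had a median of 0.64 over 24 genes (camera adjusted p = 6.3e-04; with an estimated correlation adjusted p = 0.704). The chemokine gene CCL2 rose from 1.87 ± 0.680 to 9.07 ± 2.18 CPM (edgeR adjusted p = 0.036). It was the 1 member past edgeR's threshold over all genes and adjusted over the list alone, while DESeq2 called 4 members higher. CCL2 had an edgeR adjusted p of 0.0578 without resistant replicate 1 and 0.114 without resistant replicate 2, and the list had a camera adjusted p of 0.287 without control replicate 1 (median 0.29). The NF-kB list median was 0.24 without resistant replicate 1 and 1.30 without control replicate 2.

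Interferon, antigen presentation, YAP/TEAD and keratinocyte lists were lower by camera, each with an adjusted p = 0.704 under an estimated correlation. The antigen presentation list (23 genes, median -0.27, camera adjusted p = 6.3e-04) had no member past edgeR's threshold over all genes, 9 at an unadjusted p under 0.05, 7 lower adjusted over the list alone and 6 lower with DESeq2. Its lowest values were those of MHC class II genes and their regulator CIITA, with log2 fold changes of -3.02 for HLA-DRB1, -2.77 for HLA-DRA and -2.13 for CIITA. HLA-DRA had 20.4 and 79.6 CPM in control replicates 1 and 2 and 7.34 ± 0.514 in resistant cells. Without control replicate 1 the log2 fold change was -3.67 for HLA-DRB1, -3.44 for HLA-DRA and -2.63 for CIITA. Without control replicate 2 it was -1.81, -1.47 and -1.34, so its size depended on which control was kept. These 3 genes were named after their values were seen. Neither the interferon nor the YAP/TEAD list had a member past edgeR's threshold over all genes, with 6 and 7 at an unadjusted p under 0.05 and 2 and 3 called by DESeq2. The interferon list (29 genes, median -0.41, camera adjusted p = 0.00913) had 1 gene lower adjusted over the list alone and missed the threshold without control replicate 1 (median -0.09, camera adjusted p = 0.425) and without resistant replicate 2 (0.0553). The YAP/TEAD list (23 genes, median -0.30, camera adjusted p = 0.0111) had 2 lower and 1 higher adjusted over the list alone and missed it without resistant replicate 1 (median -0.01, camera adjusted p = 0.73). Its median was -0.64 without resistant replicate 2 and -0.20 without control replicate 1. Of 10 keratinocyte genes, KRT14 fell over all genes (log2 -2.56, 1.85 to 0.312 CPM, edgeR adjusted p = 0.0355, and 0.0789 and 0.186 without resistant replicates 1 and 2; named after its values were seen) and 3 fell adjusted over the list alone (median -0.28, camera adjusted p = 0.0379). The keratinocyte list had a camera adjusted p of 0.105 without control replicate 2 and 0.258 without resistant replicate 2 (median -0.14), and a median of -0.87 without resistant replicate 1.

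**Figure D4:**
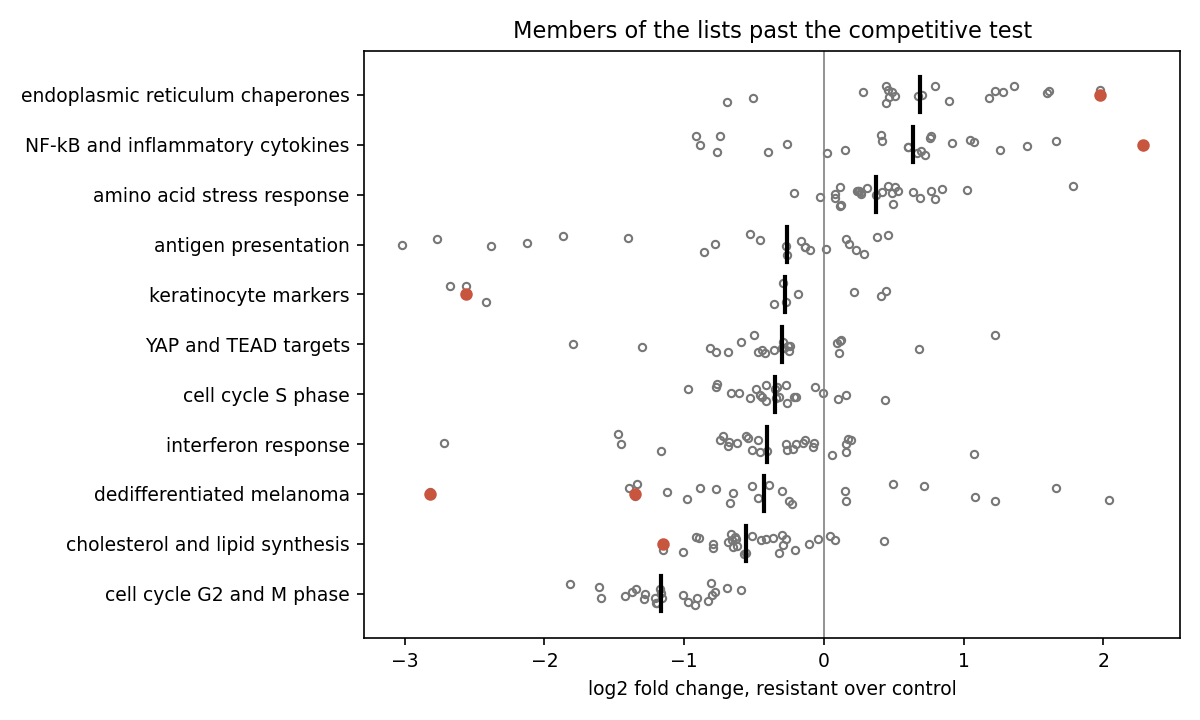
Log2 fold changes, resistant over control, of each tested member of the 11 lists past limma's camera test with a preset correlation of 0.01, with list medians as black bars. Filled points are the members past edgeR's threshold over all genes, and the G2 and M phase list has all 24 members below 0.

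Glycan genes, which bear on the surface glycan measurements the series describes, showed few changes past edgeR's threshold over all genes. DESeq2 called 5 higher and 3 lower among 35 glycosaminoglycan and proteoglycan genes, of which 14 had an unadjusted edgeR p under 0.05. The list of mucin-type O-glycosylation is described among the other observations. None of 27 N-glycan synthesis and branching genes (median 0.16, camera adjusted p = 0.322) and none of 28 sialyl- and fucosyltransferase genes (median -0.04, 0.973) passed in edgeR, over all genes or adjusted over the list alone. Each of these 2 lists had 7 genes at an unadjusted edgeR p under 0.05 and 2 lower with DESeq2. The branching enzyme gene MGAT5 had a log2 fold change of 0.26 (edgeR adjusted p = 0.609) and the core fucosyltransferase gene FUT8 one of -0.09 (0.891). The sialyltransferase gene ST6GAL1 had 60.7 ± 20.7 CPM in controls and 94.8 ± 3.21 in resistant cells (edgeR adjusted p = 0.29; log2 0.33 to 1.05 with 1 library left out). Of 12 galectin and siglec genes none passed over all genes in edgeR, 3 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone and with DESeq2 (camera adjusted p = 0.406; 0.0449 in fry's test for change in either direction, which does not compare a list with other genes). The galectin gene LGALS3 had a log2 fold change of -0.17 (edgeR adjusted p = 0.838). Among 35 glycosaminoglycan and proteoglycan genes the sulfatase gene SULF1 rose over all genes (log2 1.54, edgeR adjusted p = 0.0478, and 0.162 and 0.0942 without resistant replicates 1 and 2; named after its values were seen), and adjusted over the list alone 3 rose and 3 fell (camera adjusted p = 0.75).

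Markers of a mesenchymal or epithelial state did not pass camera, while the mesenchymal list passed fry's test for change in either direction (adjusted p = 0.0449). Of 26 mesenchymal genes the matrix metalloprotease gene MMP14 fell over all genes (log2 -1.29, edgeR adjusted p = 0.0415, and 0.225 without resistant replicate 2; named after its values were seen), with 3 lower and 1 higher adjusted over the list alone (median 0.05, mean -0.04, camera adjusted p = 0.591). VIM had a log2 fold change of -0.55 (edgeR adjusted p = 0.373) and CDH2 one of -0.34 (0.453). Of 21 epithelial genes none passed over all genes in edgeR, 4 had an unadjusted p under 0.05, and 2 rose adjusted over the list alone and with DESeq2 (median -0.13 against a mean of 0.03 and a camera test in the upward direction, adjusted p = 0.75). CDH1 was near the detection limit, at 0.219 ± 0.0331 CPM in controls and 0.371 ± 0.251 in resistant cells. ITGB4 was the 1 gene past edgeR's threshold over all genes among 19 integrins, of which 10 had an unadjusted p under 0.05. Adjusted over the list alone 3 rose and 4 fell, and DESeq2 called 1 higher and 3 lower (camera adjusted p = 0.938). COL13A1 fell among 37 collagen and matrix genes (log2 -2.33, edgeR adjusted p = 0.0206; named after its values were seen), and 3 fell adjusted over the list alone (camera adjusted p = 0.718).

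Lists for other cell types and for RNA quality did not separate the groups beyond the keratinocyte genes. Neither 13 fibroblast (camera adjusted p = 0.0521), 9 immune (0.973) nor 10 endothelial genes (0.309) passed, and none of these genes was called over all genes by edgeR. Adjusted over the list alone 3 fibroblast genes fell and 1 rose, 1 endothelial gene fell and no immune gene changed. DESeq2 called 1 fibroblast gene higher and 2 lower, 1 endothelial gene higher and 1 lower and 0 immune genes, and 7, 3 and 0 of the fibroblast, endothelial and immune genes had an unadjusted edgeR p under 0.05. The RNA quality list (18 genes) had a median of 0.05 (camera adjusted p = 0.75). Mitochondrial transcripts took 5.67% and 4.89% of counts in the controls and 5.22% and 4.81% in the resistant libraries.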

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

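Halving control replicate 1, halving all counts, DESeq2 with control replicate 1 halved, and leaving out the genes of the chromosome 3 and 7 segments were chosen after seeing the data. The other alternatives were planned. The count of 272 changed genes became 1210 with DESeq2 (269 of the 272 shared), 1866 without the filter on low counts, 440 with all counts halved and 1189 with DESeq2 and control replicate 1 halved. It ranged from 16 to 2166 with 1 library left out. The 266 genes changed at least 2-fold became 899, 1327, 404 and 892 under the same 4 settings, 30 with glmTreat, and 16 to 1761 with 1 library left out. Other scalings, limma-voom, the stricter filter, protein-coding genes alone, thinned counts and halving control replicate 1 gave 211 to 325 changed genes. The 11 lists became 0 with an estimated correlation (lowest unadjusted p 0.115) and 0 with fry's directional test, and 9 to 15 under the remaining settings. Fry's test for change in either direction passed 4 lists, none of them among the 11: mucin-type O-glycosylation (adjusted p = 0.0323), drug transporters (0.0323), galectins and siglecs (0.0449) and mesenchymal markers (0.0449). The cause was not tested, except that glmTreat asks for more than the main test and that a left-out library changes the estimate of spread. At an unadjusted p under 0.05 edgeR had 3360 genes. The segment medians ranged from 0.95 to 1.03 on chromosome 7 and from -0.66 to -0.57 on chromosome 3 over all settings. With the replicate number as a block, 64 genes were called and 64 at least 2-fold (58 shared with the 272), with 1 residual degree of freedom fewer. The deviations of replicates with the same number had a Pearson r of 0.002 across genes over 2 pairs. The second principal component, with 17% of the variance, did separate the numbers (8.13 and 14.1 for control and resistant replicate 1, -14.7 and -7.55 for replicate 2). The labels tie the numbers to no batch or day, so they are not taken to pair the libraries. Under the block BRAF, PPARG and 11 other named genes lost their calls, and the keratinocyte list its own (camera adjusted p = 0.0535, between 0.014 and 0.704 over all alternatives).

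Of the 30 called named genes, none changed sign in any alternative. Without resistant replicate 2, 7 kept their call, without resistant replicate 1, 28 did, and without either control all 30 did. Calls were also lost by PDIA4 with library size alone, upper-quartile factors, the stricter filter, protein-coding genes alone and thinned counts, by WNT5A with library size alone and upper-quartile factors, by ACAN and PAPPA with upper-quartile factors, the stricter filter and protein-coding genes alone, by WSCD1 with the stricter filter, and by BMX and TM4SF18 with limma-voom. Genes that changed sign did not pass the test as reported or under the setting that turned them. SOX10 had a log2 fold change of 0.01 with library size alone, 0.02 with upper-quartile factors, 0.02 with limma-voom, 0 without the filter and 0.03 with the block. ABCB5, near the detection floor, had 0.98 with limma-voom and 0.37 with the block. With 1 library left out, the log2 fold change ranged from -0.32 to 0.38 for SOX10, -1.35 to 0.02 for NGFR, -0.40 to 0.29 for DUSP6, -0.15 to 1.16 for SPRY4, -0.55 to 0.20 for CCND1, -1.51 to 5.95 for ABCB5, -0.17 to 1.32 for CDH1, -0.17 to 0.01 for FUT8 and -0.52 to 0.13 for LGALS3. The dedifferentiation list missed the camera threshold with the segment genes left out (adjusted p = 0.0668; 4.93e-06 to 0.704 over its alternatives) and with the stricter filter (0.0537), as did the interferon list with the stricter filter (0.0667; 0.0023 to 0.704) and the keratinocyte list without the filter (0.0503). Agreement with the authors' deposited table is only described, among the other observations, and its alternatives were not run, because that table names no comparison. Depth did not limit most named genes: CDH1 and ABCB5 alone among the 48 were under 1 CPM in both groups.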

Other observations

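Tests chosen only after the result was seen were those of BRAF without control replicate 1, of one share of resistant RNA in control replicate 2, of sampling noise in control replicate 1, and of the G2 and M phase list without control replicate 1. The others were set before their values were seen.

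Several lists outside the report had changed members. Among 16 drug transporter genes ABCB8 rose (log2 1.27, edgeR adjusted p = 0.0247) and ABCB4 fell (log2 -2.39, edgeR adjusted p = 0.0355), both named after their values were seen, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.251; 0.0323 in fry's test for change in either direction). ABCB8 lies in the chromosome 7 segment, whose genes had a median log2 fold change of 0.99. Without resistant replicate 2, ABCB8 had an edgeR adjusted p of 0.148 and ABCB4 of 0.174, and without resistant replicate 1 ABCB4 had 0.0753. ABCB5 had at most 0.243 CPM in any library. Among 15 genes of histone demethylases and slow cycling, ALDH1A1 rose from 0.211 to 1.79 CPM (edgeR adjusted p = 0.036, and 0.0804 and 0.109 without resistant replicates 1 and 2), named after its values were seen, and 3 rose adjusted over the list alone (camera adjusted p = 0.113). The NOTCH ligand gene DLL1 rose (log2 1.87, edgeR adjusted p = 0.0488; camera adjusted p = 0.322 for 19 genes), as did the carbonic anhydrase gene CA12 among 22 hypoxia genes (log2 3.51, edgeR adjusted p = 0.0312; camera adjusted p = 0.946), both named after their values were seen. DLL1 had an edgeR adjusted p of 0.114 and 0.217 without resistant replicates 1 and 2, and CA12 had 0.132 without resistant replicate 2 and a log2 fold change of 4.54 without control replicate 2.

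Cell cycle inhibitor and p53 target genes had 5 of 19 members higher adjusted over the list alone and 0 over all genes in edgeR, with 8 at an unadjusted p under 0.05 and 2 higher with DESeq2 (median 0.43, camera adjusted p = 0.0521). Of these CDKN1A had 253 CPM in controls and 398 in resistant cells and AEN 85.4 and 177. With 1 library left out, the log2 fold change ranged from 0.49 to 0.84 for CDKN1A and from 0.70 to 1.36 for AEN. The list of mucin-type O-glycosylation (18 genes, median 0.39) had a camera adjusted p of 0.0521 and one of 0.0323 in fry's test for change in either direction. No gene of it passed edgeR's threshold over all genes, 5 had an unadjusted p under 0.05 and 2 were higher with DESeq2. Adjusted over the list alone 2 rose, GALNT12 (log2 1.14, edgeR adjusted p over all genes 0.102) and GALNT18 (log2 1.15, 0.12). With 1 library left out, their log2 fold changes ranged from 0.95 to 1.31 and from 0.91 to 1.44. Glycolysis (24 genes, median -0.20, camera adjusted p = 0.0626), oxidative phosphorylation (34 genes, 0.592), oxidative stress (21 genes, 0.75), heat shock (16 genes, 0.75), TGF-beta (23 genes, 0.276), WNT (24 genes, 0.915) and apoptosis genes (26 genes, 0.463) did not pass camera. Of their members WNT5A alone was called over all genes by edgeR.

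The authors' deposited table of fold changes lists 1533 genes, 686 positive and 847 negative, none smaller than 0.4 in size. Of the 1395 genes of the authors' deposited table that were tested here, 1393 had the same sign as resistant over control, with Pearson's r of 0.959 and Spearman's rho of 0.989 across genes, which are not independent replicates. The authors' deposited table holds 222 of the 272 changed genes. Its genes in the chromosome 7 segment were positive in 54 of 55 cases and those in the chromosome 3 segment negative in 188 of 190, in the authors' deposited table. If that table was made from these same libraries, such agreement was bound to arise. It therefore adds no separate evidence for the segments.

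BRAF and the genes of 2 chromosome segments changed together. Gain of the chromosome 7 segment is a candidate explanation for the first. The 10 nearest genes of BRAF had a median log2 fold change of 0.95, where the 95th percentile of such medians over all genes was 0.27. These neighbours lie in the segment, so their median largely restates its rise. Among genes that had no part in finding it, 35 in the segment had a median of 1.06 ± 0.109 (bootstrap SE) relative to such genes elsewhere. Loss of chromosome 3 DNA may account for the second, where 111 genes that had no part in finding the segment had a median of -0.62 ± 0.049 (bootstrap SE) relative to such genes elsewhere. Both bootstraps resampled genes as if neighbours were independent, so the SEs hold no spread between libraries. The genes checked come from the same 4 libraries and are no independent sample. The tables argue against GC content or length bias, since the medians were 0.97 and -0.60 after removing that trend. The CPM assigned to the pseudogene BRAFP1 changed by -0.064% of the gain of BRAF. That value leaves out any BRAFP1 reads placed on BRAF, so it does not decide whether such reads were counted for BRAF. BRAF kept a log2 fold change of 1.07 without control replicate 1, so its rise does not rest on that library alone. This decides nothing about double counting there, since doubling all counts of a library cancels in the scaling to library totals. DNA was not measured, and a subclone selected under the drug, a gain during culture and regulation over a long stretch stay open.

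Control replicate 2 lay between control replicate 1 and the resistant libraries. On the first principal component, with 68.7% of the variance, control replicate 2 was at -7.07, control replicate 1 at -35.2 and the resistant libraries at 23.1 and 19.2. RNA of resistant cells in control replicate 2 would give one share in all genes nearly lost in resistant cells, but the interquartile range of log2 control 2 over control 1 was 1.96 in 7 such genes, and on the raised chromosome 7 segment that ratio was 0.02 with a bootstrap SE of 0.0495. Sampling noise in control replicate 1 is argued against as the whole of it, with that library split at random into 2 parts of independent sampling error. The covariance across genes of control replicate 2 and the resistant mean, each minus a different part, was taken. It was 53.6% ± 1.24 (bootstrap SE over genes) of that of the resistant mean minus either part, where sampling alone would give about 0. Any other deviation of control replicate 1 alone is in both parts and raises this share. The share therefore does not place control replicate 2 between the groups. A difference in density, passage or handling of the control cultures may also remain, and no biological explanation was tested.

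The G2 and M phase list was lower in resistant cells. The list median was -0.69 without control replicate 1 and -1.46 without control replicate 2. The fall was therefore not in control replicate 1 alone, though its size depended on that library. With 1 control left, spread between control libraries cannot be told from a difference between the groups. The highest list median over 3 other scalings was -1.13, which decides nothing, since these scalings gave all genes a median of at most 0.048. Slower growth of the resistant cells is a hypothesis that may account for it, and growth was not measured here. A difference in culture density or harvest time stays open, as 2 libraries per group cannot exclude it.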
